A study of Mus musculus with 9 samples.

How the data were processed

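RNA from whole lung of C57BL/6 mice was sequenced after poly(A) isolation, with a strand-specific library kit, in 9 samples that form 3 groups of 3. The groups were normoxia (replicates 2, 3 and 5), hypoxia (replicates 1, 2 and 5) and hypoxia with parathyroid hormone, PTH (replicates 3, 4 and 5). Per the labels, hypoxic mice spent 3 weeks in a chamber at 10% oxygen, and the treated group received the peptide of residues 1 to 34 of PTH at 40 µg/kg per day. A sham group given saline is mentioned in the labels, which do not say which samples it comprises. The labels do not state that each sample came from a separate animal, so p-values measure the spread between samples.

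The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.9a and the mouse genome build mm10. The read counter, its use of the strand and the gene annotation are not given in the sources used here. The deposited table holds 53342 genes with 2 values per sample. The deposited read counts are estimated counts (expected counts), since only 11.4% of those above 0 were whole numbers. The deposited normalized values are log2 TPM with a floor of 1 TPM, as the powers of 2 of the values above 0 summed to 997249 to 997533 per sample. Symbols came from the table itself, and positions are those of the table, which matched a GENCODE M21 annotation of the same build at 96.31% of the 53237 gene IDs found there. No gene of the mitochondrial chromosome was in the table.

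Totals ran from 40234030 to 58391086 counts per sample. Of the whole counts of 1 to 20, 88.8% were even, so mates of a pair seem to have been counted individually. The totals would then exceed the number of fragments, and the minimum count of 10 would stand for fewer fragments than that. Counts were not corrected for this. They were rounded and analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust dispersion and the quasi-likelihood F test, in 1 model of all 9 samples with 6 residual degrees of freedom. The filter kept 19640 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, over all genes tested in each comparison. The common biological coefficient of variation was 0.2, and the median standard error of a log2 fold change was 0.17 in each comparison. Expression is given as CPM, the counts scaled by TMM library sizes, as mean and SD of 3 samples, and fold changes as log2 values with their standard error (SE).

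The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule, each comparison names Pth1r, then the 10 genes with the largest rise and the 10 with the largest fall among genes called changed whose groups do not overlap and whose higher mean is at least 5 CPM, predicted genes left out. Where fewer than 3 pass in a direction, the 5 with the smallest p are given as values. Up to 4 members with the smallest p are added for each list that was called or has several called members. The text describes a part of these.

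The 46 gene lists cover cell types and pathways. Each was tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at its preset correlation of 0.01 between genes of a list, which compares the list with all other genes, and p was adjusted over the lists. Camera with the correlation estimated for each list, and fry, were run beside it. The PValue of fry tests whether the genes of a list move, on balance, one way, and its PValue.Mixed whether they change in either direction. Each list's members were also adjusted over the list alone.

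On simulated data with 3 samples per group made from these libraries, edgeR recovered 40.3 to 55.2% of genes changed 2-fold and 75.8 to 78.8% of genes changed 4-fold, with 3 to 6 false calls. DESeq2 1.42.0 made 29 to 42 false calls on the same data. Camera called a shifted list and 0 other lists in each comparison. Genes were simulated independently of each other, while the correlation estimated within the cardiac list was 0.85. The simulation therefore does not measure how often camera calls unchanged lists in these libraries.

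Alternatives covered DESeq2 size factors, the DESeq2 and limma-voom tests, no filter and a stricter filter, only the 6 samples compared, the replicate number as a block, and each sample left out in turn. Further alternatives were a threshold of 0.1, a minimum absolute log2 fold change of 1, and limma-trend on TPM with pseudocounts of 0.1 and 5, quantile normalization or median centring. After the data were seen, limma-trend on the deposited log2 values and 2 covariates per library were added. The muscle and fat score is the mean centred log2 CPM of cardiac muscle and adipocyte markers. The clock score is the mean of Dbp, Per3, Tef, Hlf, Nr1d1 and Nr1d2 minus that of Arntl, Npas2 and Clock. Replicate numbers were not treated as pairs in the main model. Correlations of the residuals of samples with the same number lay between -0.097 and 0.14, but such pairs are too few to exclude a shared factor. The clock score was low in replicate 5 of both normoxia (-2.47) and hypoxia (-2.09), against 2.40 to 3.22 in the other libraries of those groups. For comparisons that share a group, simulated libraries with no effect, or with a hypoxia effect and no PTH effect, gave the values expected from the shared group in 25 runs each.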

Results

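Gene expression was measured by poly(A) RNA sequencing of whole lung in 3 groups of 3 C57BL/6 samples. The mice were kept in room air (normoxia), at 10% oxygen for 3 weeks (hypoxia), or at 10% oxygen with daily injections of parathyroid hormone (PTH), a peptide hormone that raises blood calcium through bone and kidney. Totals were 51490433, 58391086 and 46932520 counts in normoxia replicates 2, 3 and 5. They were 40234030, 45627036 and 54502468 in hypoxia replicates 1, 2 and 5, and 41619965, 44181821 and 43169696 in PTH replicates 3, 4 and 5. Of the whole counts of 1 to 20, 88.8% were even, so mates of a pair seem to have been counted individually and these totals would exceed the number of fragments. After filtering, 19640 genes were tested. The first principal component of log2 CPM held 27.2% of the variance and ran from -52.5 in normoxia replicate 2 to 59.1 in PTH replicate 5.

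Marker genes showed that libraries differed in clock phase and in muscle and fat content within groups. Dbp, a clock output gene, stood at 197 and 160 CPM in normoxia replicates 2 and 3 and at 316 and 197 CPM in hypoxia replicates 1 and 2. It was 6.85 CPM in normoxia replicate 5, 13.9 CPM in hypoxia replicate 5, and 10.4, 16.5 and 6.13 CPM in the PTH libraries. Arntl, which encodes the clock activator BMAL1, had the opposite pattern, with 1.77 to 4.64 CPM in the libraries rich in Dbp and 41.3 to 50.1 CPM in the others. Myh6, a cardiac myosin gene, ran from 6.86 CPM in PTH replicate 5 to 758 CPM in hypoxia replicate 5, and Adipoq, an adipocyte gene, from 0.0947 CPM in PTH replicate 5 to 17.37 CPM in hypoxia replicate 2. The list of genes linked to sex was not called by camera in any comparison (adjusted p = 0.151, 0.798 and 0.126). It holds Xist and Tsix beside Y chromosome genes, whose opposite changes a one-way test can miss. Fry's test for change in either direction did not call it either (adjusted p = 0.801, 0.931 and 0.328).

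**Figure D1:**
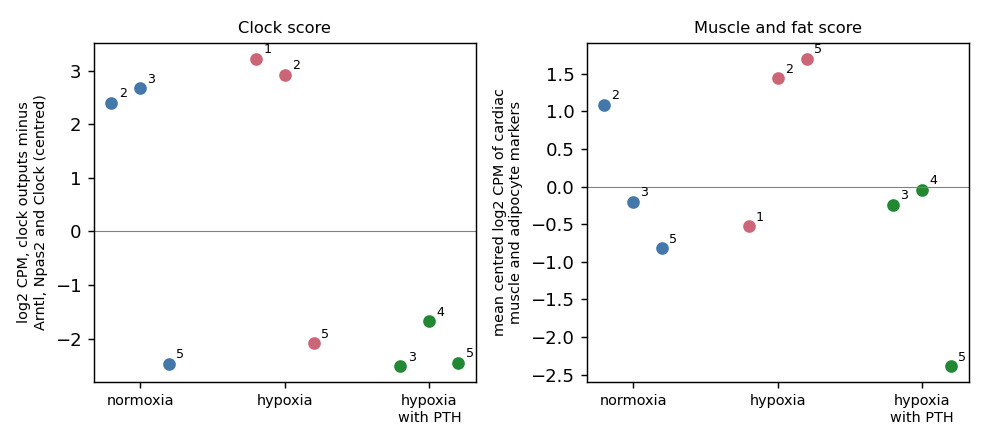
Clock score (left) and muscle and fat score (right) of each library, both in log2 CPM, by group, with each point labelled by its replicate number. The clock score was -2.47 in normoxia replicate 5, -2.09 in hypoxia replicate 5 and -2.52 to -1.68 in the PTH libraries, against 2.40 to 3.22 in the other 4, and the muscle and fat score was lowest in PTH replicate 5 (-2.39).

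The title of the series names the PTH receptor in hypoxic lung, and its gene, Pth1r (ENSMUSG00000032492, mm10 chromosome 9, 110722085 to 110747145, minus strand), was measured in all 3 groups. Pth1r stood at 3.81 ± 0.503 CPM in normoxia, 4.80 ± 0.647 CPM in hypoxia and 6.88 ± 0.411 CPM in hypoxia with PTH (mean ± SD, n = 3 each). It rose in hypoxia with PTH against normoxia, with a log2 fold change of 0.85 (SE 0.17, edgeR adjusted p = 0.0356 over all genes and 0.0067 adjusted over the list alone). Hypoxia against normoxia gave 0.33 (SE 0.17, edgeR adjusted p = 0.487), and hypoxia with PTH against hypoxia 0.52 (SE 0.17, unadjusted p = 0.0111, edgeR adjusted p = 0.451 and DESeq2 adjusted p = 0.107), so neither passed the test. The 3 hypoxia libraries (4.132, 4.851 and 5.423 CPM) stood above the highest normoxia library (4.126 CPM), the first by a margin far smaller than the SD. A two-sided exact permutation test gave p = 0.1 in each comparison, the smallest p that 3 against 3 allows. Of the 14 measured genes of PTH signalling, which include the ligand, receptor and G protein genes, Pth1r alone was called changed, against normoxia in hypoxia with PTH, and 0 were called in the other comparisons by edgeR. The list had camera adjusted p of 0.56, 0.465 and 0.337 for hypoxia, PTH against hypoxia and PTH against normoxia. Fry's test for change in either direction gave adjusted p of 0.129, 0.525 and 6.51e-05. The list thus passed it in hypoxia with PTH against normoxia, where its members ran from -1.47 to 0.85.

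The Pth1r call against normoxia was lost without normoxia replicate 2 (adjusted p = 0.0931), 3 (0.102) or 5 (0.082), without hypoxia replicate 2 (0.0554), and without PTH replicate 3 (0.0741), 4 (0.0748) or 5 (0.137). It was also lost with only the 6 libraries compared (0.0638), with the replicate number as a block (0.265), and with the muscle and fat score (0.0596) or the clock score (0.156) as a covariate. The block leaves far fewer residual degrees of freedom than the main model. A covariate also uses a degree of freedom, and the clock score overlaps with this comparison. The loss with the clock score therefore cannot be told apart from lost power. The log2 fold change of Pth1r stayed between 0.75 and 0.91 with each library left out. Over all alternatives the adjusted p ran from 6.81e-05 to 0.265. Pth1r overlaps Myl3, a cardiac myosin light chain gene on the other strand with 83.1% of its mean TPM. Myl3 did not follow Pth1r across libraries: it was lowest in PTH replicate 5 (0.0947 CPM), where Pth1r stood at 7.22 CPM, and highest in hypoxia replicate 5 (9.11 CPM).

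The comparison of hypoxia with normoxia asks how the lung differs after 3 weeks of low oxygen. Ntrk2, which encodes the neurotrophin receptor TrkB, rose from 5.72 ± 1.13 to 210 ± 52 CPM (mean ± SD, n = 3 each), a log2 fold change of 5.20 (SE 0.32). Genes of the matrix and its cells rose: Mfap4, a microfibril protein gene, by 2.11 (SE 0.12) from 291 ± 37.7 to 1260 ± 132 CPM, Aspn, which encodes asporin, by 1.97 (SE 0.22), and Fn1, the fibronectin gene, by 0.78 (SE 0.079). Among endothelial genes, Plvap, which encodes the diaphragm protein of fenestrae and caveolae, fell from 569 ± 94.1 to 87.7 ± 27.7 CPM (-2.70, SE 0.26). Esm1 also fell (-3.35, SE 0.305), as did Cd300lg (-1.75, SE 0.195), the chemokine gene Cx3cl1 (-1.51, SE 0.15) and the Notch ligand gene Dll4 (-1.17, SE 0.14). The endothelial sialomucin gene Emcn rose by 0.99 (SE 0.13), and the chemokine gene Cxcl12 by 1.86 (SE 0.22). Slc26a10 (4.87, SE 0.12), Fam181b (2.69, SE 0.25) and Adam23 (2.01, SE 0.21) also rose, and Ivns1abp (-1.40, SE 0.12) and Samd5 (-1.32, SE 0.16) fell. All of these genes had edgeR adjusted p between 4.18e-08 and 0.00694, and each stayed called with any of the 9 libraries left out, with adjusted p up to 0.0415. With the replicate block, Ntrk2, Slc26a10, Mfap4, Aspn, Plvap and Cxcl12 stayed called. The other genes named in this paragraph so far lost their calls with it (edgeR adjusted p from 0.0858 to 0.138). Slc26a10 overlaps B4galnt1, and Dll4 overlaps Gm14207, on the other strand. B4galnt1 had -0.32 (adjusted p = 0.308) and Gm14207 -1.03 (adjusted p = 0.107).

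**Figure D2:**
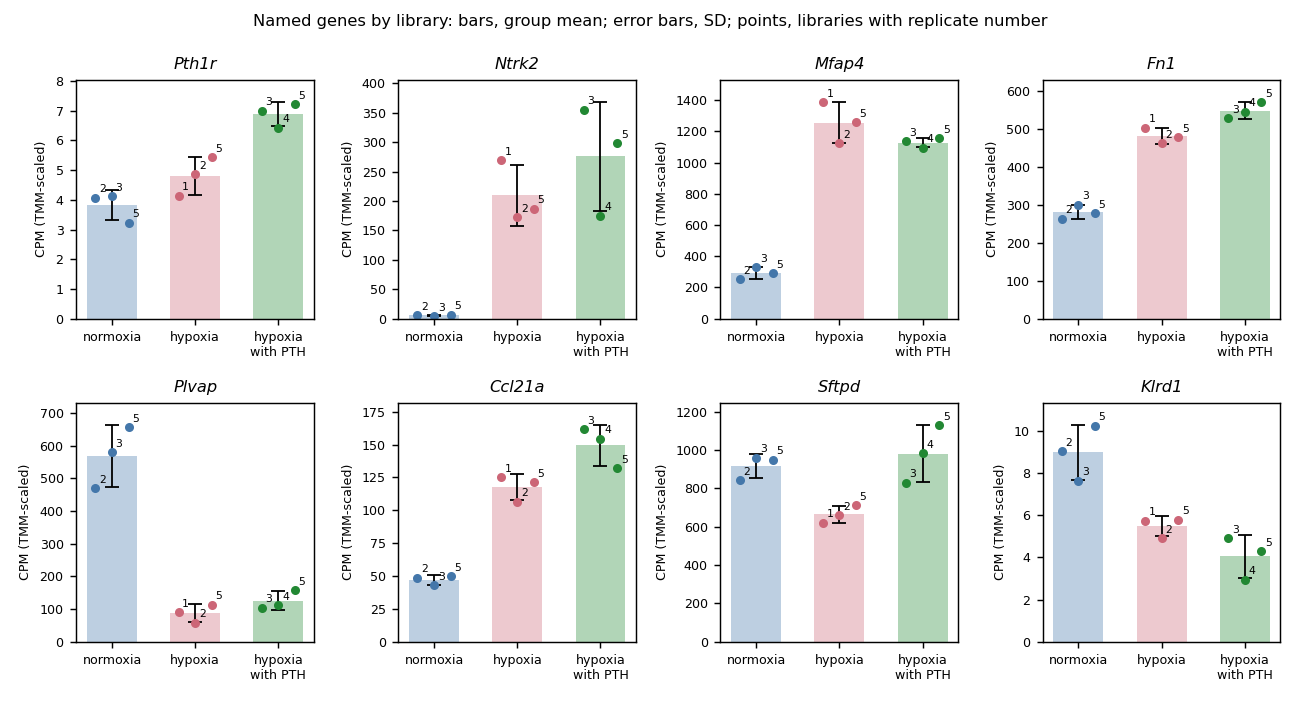
Expression in TMM-scaled CPM of 8 named genes by group, with bars for the mean, error bars for the SD and a point per library labelled with its replicate number. Ntrk2, Mfap4, Fn1 and Ccl21a were higher and Plvap lower in all 3 hypoxia and all 3 PTH libraries than in normoxia, and Pth1r was highest in the 3 PTH libraries (6.42 to 7.22 CPM).

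In all, 112 genes were called changed between hypoxia and normoxia, 81 higher and 31 lower, and 60 of them by a log2 fold change of at least 1 in size. At an unadjusted p under 0.05 there were 2321 genes, against 982 by chance, and the 2 groups did not overlap for 17.1% of genes, where chance gives 10%. Both chance values, here and for the other comparisons, are averages. Genes that move together widen the spread around them, and other splits of the libraries were not counted in these ways. Leaving out normoxia replicate 3, hypoxia replicate 1 or hypoxia replicate 5 left 50, 52 or 70 genes. DESeq2 called 795 and a test without the filter 198. Limma-trend on TPM gave more even directions with quantile normalization (64 higher and 43 lower) and median centring (54 higher and 43 lower). These fits also differ from edgeR in test, measure and filter, so the evenness cannot be credited to the normalization.

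Lists of matrix, pericyte, lymphatic, fibroblast and aerocyte genes were among those that moved in hypoxia, while capillary, arterial and venous endothelial markers were not called as lists moving one way (camera adjusted p = 0.986, 0.164 and 0.769). Capillary and arterial genes did pass fry's test for change in either direction (adjusted p = 1.24e-05 and 4.71e-06), with 1 higher and 1 lower, and 3 higher and 1 lower, called over all genes. In the extracellular matrix list 33 of 42 genes had values above 0, with a median log2 fold change of 0.46. Of these genes, 3 rose over all genes tested, and 18 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.52e-08, and adjusted p = 0.449 with an estimated correlation). Pericyte markers rose as a list (median 0.32, 11 of 14 above 0, camera adjusted p = 0.000121, and adjusted p = 0.373 with an estimated correlation). Of the pericyte genes 3 were called over all genes, and 8 rose and 1 fell when adjusted over the list alone. Among those that rose was Cspg4, the NG2 proteoglycan gene (0.92, SE 0.12, adjusted p = 0.00694). Higd1b rose by 0.79 (SE 0.11, adjusted p = 0.012), a call lost without normoxia replicate 3 (0.0578) or hypoxia replicate 1 (0.0594). Lymphatic endothelial markers rose as a list (median 0.41, 7 of 11 above 0, camera adjusted p = 0.0152, and adjusted p = 0.454 with an estimated correlation). That call was lost without hypoxia replicate 2 (0.0778). Of these, 3 were called over all genes and 5 rose and 2 fell when adjusted over the list alone. Prox1, the lymphatic transcription factor gene, rose by 1.55 (SE 0.20, adjusted p = 0.00863) and the chemokine gene Ccl21a by 1.32 (SE 0.10, adjusted p = 0.000708), though Ccl21a has near-identical paralogs that can share reads. Lyve1 had -2.29 (SE 0.39, adjusted p = 0.0529). Fibroblast markers rose as a list (median 0.24, camera adjusted p = 0.00433, and adjusted p = 0.449 with an estimated correlation). It was lost without normoxia replicate 5 (0.129), where the mean score difference fell to 0.19 from 0.32. Of 18 fibroblast genes 1 was called over all genes, and 2 rose and 1 fell adjusted over the list alone. Aerocyte markers fell as a list (median -0.24, camera adjusted p = 0.0216, and adjusted p = 0.449 with an estimated correlation). It was lost without normoxia replicate 3 (0.081), normoxia replicate 5 (0.121) or hypoxia replicate 2 (0.203), the last of which moved the mean score difference to -0.11 from -0.19. It was also lost with the muscle and fat score as a covariate (median -0.17). Of 13 aerocyte genes 2 fell over all genes and also adjusted over the list alone, one of them Cyp4b1 (-0.86, SE 0.11, adjusted p = 0.00756, and 0.0501 without hypoxia replicate 1).

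Markers of lymphoid cells and red cells were called lower in hypoxia by camera at its preset correlation. Fry's one-way test did not call the B cell, NK, T cell, plasma cell or erythroid list (adjusted p from 0.162 to 0.21). In the B cell list 16 of 17 genes had values below 0 (median -1.16), 1 fell over all genes tested and 14 fell when adjusted over the list alone (camera adjusted p = 3.47e-11, and adjusted p = 0.449 with an estimated correlation). All 16 genes of NK and cytotoxic cells had values below 0 (median -0.99), 0 were called by edgeR over all genes and 11 fell adjusted over the list alone (camera adjusted p = 5.97e-09, and adjusted p = 0.449 with an estimated correlation). T cell markers fell as a list (median -0.53, 19 of 20 below 0, 0 called over all genes or adjusted over the list alone by edgeR, camera adjusted p = 1.15e-06, and adjusted p = 0.459 with an estimated correlation). Plasma cell markers fell too (median -0.80, 0 called by edgeR over all genes and 3 adjusted over the list alone, camera adjusted p = 0.000683, and adjusted p = 0.449 with an estimated correlation). Erythroid markers fell as a list (median -0.66, 0 called by edgeR over all genes and 7 adjusted over the list alone, camera adjusted p = 9.31e-05, and adjusted p = 0.449 with an estimated correlation). Hbb-bs, a beta globin gene with close paralogs, stood at 1900 ± 188 CPM in normoxia and 1180 ± 160 CPM in hypoxia (n = 3 each, -0.69, SE 0.17, edgeR adjusted p = 0.113). Antigen presentation genes rose as a list (median 0.51, 17 of 19 above 0, camera adjusted p = 4.34e-08, and adjusted p = 0.449 with an estimated correlation). In that list 2 rose over all genes, and 13 rose and 1 fell adjusted over the list alone. Its class II regulator gene Ciita had 1.78 (SE 0.29, adjusted p = 0.0375), and each of the 6 libraries compared ended that call when left out (0.0652 to 0.16). Ciita overlaps Dexi on the other strand, which has 132% of its mean TPM and had 0.22 (adjusted p = 0.587). Type 2 alveolar cell markers fell slightly as a list (median -0.12, 14 of 15 below 0, camera adjusted p = 0.00294, and adjusted p = 0.449 with an estimated correlation), 0 over all genes by edgeR and 3 adjusted over the list alone. Cell cycle genes rose as a list (27 of 32 above 0, median 0.19, camera adjusted p = 0.00433, and adjusted p = 0.615 with an estimated correlation). Of these, 0 were called by edgeR over all genes and 1 rose adjusted over the list alone. The cell cycle call was lost without normoxia replicate 2 (0.0761) or hypoxia replicate 1 (0.116).

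Cardiac muscle markers were called higher in hypoxia as a list (16 of 18 above 0, median 0.97, 0 by edgeR over all genes or adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.713 with an estimated correlation), and adipocyte markers had a median of 0.92 (11 of 11 above 0, camera adjusted p = 0.0723). The mean score difference of adipocyte markers (0.74) moved with each library compared: it was 1.34, 0.44 and 0.45 without normoxia replicates 2, 3 and 5, and 1.68, 0.24 and 0.30 without hypoxia replicates 1, 2 and 5. The cardiac call was lost without normoxia replicate 5 (0.277), hypoxia replicate 2 (0.0801) or hypoxia replicate 5 (0.236). The cardiac mean score difference of 0.91 was 1.40 without normoxia replicate 2, 0.40 without normoxia replicate 5, 1.46 without hypoxia replicate 1 and 0.50 without hypoxia replicate 5.

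Camera called 20 of 46 lists between hypoxia and normoxia, 10 up and 10 down, and 0 with an estimated correlation. By fry's one-way test pericyte markers alone passed (adjusted p = 0.0113), and by its test for change in either direction 18 lists passed. Another split of the same 6 libraries called up to 18 lists, against 20 in the real split.

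**Figure D3:**
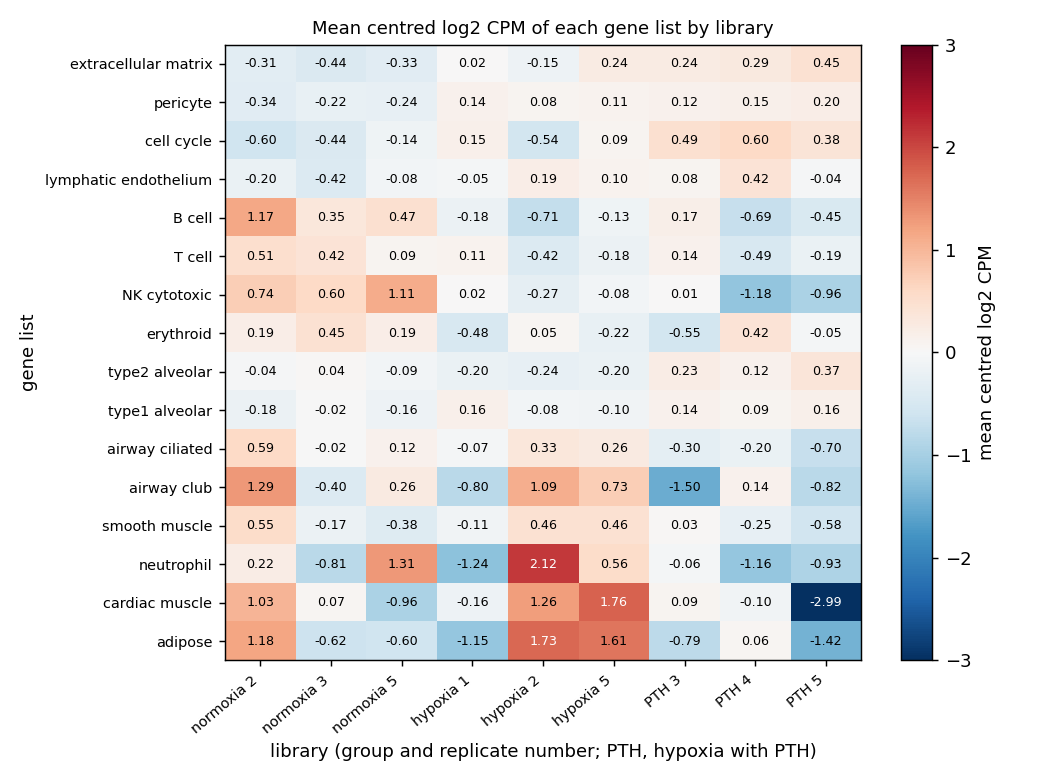
Mean centred log2 CPM of 16 gene lists (rows of the map) in each of the 9 libraries (columns, by group and replicate number), with colour from low (blue) to high (red). The matrix list ran from -0.44 to -0.31 in normoxia, from -0.15 to 0.24 in hypoxia and from 0.24 to 0.45 with PTH, and the type 2 alveolar list from -0.24 to -0.20 in hypoxia and from 0.12 to 0.37 with PTH.

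The comparison of hypoxia with PTH against hypoxia asks how hypoxic lung differed with daily PTH. The labels do not say whether the hypoxia samples were given saline, so an effect of the injections cannot be excluded. By edgeR 0 genes were called changed at an adjusted p under 0.05 and 0 under 0.1, with 1828 genes at an unadjusted p under 0.05 against 982 by chance. Among the genes with the smallest p that were higher with PTH were the transcription factor gene Irx1, with 192 ± 16.2 against 120 ± 10.5 CPM (n = 3 each, 0.68, SE 0.09), and the kinase anchor gene Akap12 (0.52, SE 0.07), each with edgeR adjusted p = 0.125. The cytokine receptor gene Il1r1 (0.57, SE 0.087) and Pvr (0.59, SE 0.09) followed, each with adjusted p = 0.23. Among those lower, Rgs3, a regulator of G protein signalling, had -0.49 (SE 0.078, adjusted p = 0.231), Bcl7a -0.49 (SE 0.081, adjusted p = 0.234), Tsku -0.75 (SE 0.12, adjusted p = 0.237), Cfap161 -0.82 (SE 0.15, adjusted p = 0.36) and AC160336.1 -2.16 (SE 0.38, adjusted p = 0.36). Limma-voom called 0 genes and DESeq2 156, 95 higher and 61 lower. In the simulation of this comparison DESeq2 made 29 false calls among 143. Limma-trend on TPM called 3 to 6 genes, among them the predicted genes Gm26247, Gm23991 and Gm45332 in each of its 5 settings, and Akap12 and Irx1 with median centring. Leaving out hypoxia replicate 5 gave 1 gene, Trp53i11 (1.31, adjusted p = 0.0434), and the 4 genes outside the naming rule were chosen after their values were seen. The 2 groups did not overlap for 13.9% of genes, where chance gives 10%.

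By list, markers of type 2 alveolar cells, which make surfactant, were higher with PTH. All 15 genes had values above 0 (median 0.43), 0 were called by edgeR over all genes and 14 rose when adjusted over the list alone (camera adjusted p = 2.21e-13, and adjusted p = 0.236 with an estimated correlation). It was the single list to pass fry's one-way test (adjusted p = 0.0259). Sftpd, the surfactant protein D gene, stood at 980 ± 150 CPM with PTH and 664 ± 45.7 CPM in hypoxia (n = 3 each, 0.56, SE 0.12, edgeR adjusted p = 0.366), and the lipid transporter gene Abca3 at 454 ± 18.1 and 316 ± 34.5 CPM (0.52, SE 0.11, adjusted p = 0.366). Cell cycle genes rose again as a list (28 of 32 above 0, median 0.62, 0 called by edgeR over all genes or adjusted over the list alone, camera adjusted p = 4.76e-11, and adjusted p = 0.628 with an estimated correlation). The mean score difference of 0.59 was 0.37 without hypoxia replicate 2, and the median was 0.37 with the clock score as a covariate. Kif11, a mitotic motor gene, had 1.18 (SE 0.36, adjusted p = 0.433). Matrix genes rose again (32 of 42 above 0, median 0.29, 0 over all genes by edgeR and 5 adjusted over the list alone, camera adjusted p = 1.52e-06, and adjusted p = 0.628 with an estimated correlation). The metalloproteinase gene Mmp14 had 0.77 (SE 0.18, adjusted p = 0.426) and the collagen gene Col5a2 0.63 (SE 0.17, adjusted p = 0.426). A list of immediate genes that the messenger cAMP can induce rose (16 of 18 above 0, median 0.60, 0 over all genes by edgeR and 2 adjusted over the list alone, camera adjusted p = 0.000286, and adjusted p = 0.628 with an estimated correlation). Its median was 0.44 with the clock score as a covariate, and whether cAMP or the PTH receptor raised these genes was not tested. The call of the cAMP list was lost without hypoxia replicate 1 (0.064). The list's score was -1.26 in that library, against -0.28 and 0.26 in the other hypoxia libraries and -0.39, 0.36 and 0.83 with PTH. The mean score difference of 0.69 was 0.28 without hypoxia replicate 1 and 0.41 without PTH replicate 5. With PTH against hypoxia the growth factor gene Areg had 1.80 (SE 0.44, adjusted p = 0.426) and Crem 0.65 (SE 0.15, adjusted p = 0.426). In hypoxia against normoxia the same cAMP list was called lower (16 of 18 below 0, median -0.35, 0 over all genes by edgeR and 1 adjusted over the list alone, camera adjusted p = 0.00261, and adjusted p = 0.615 with an estimated correlation). That call too was lost without hypoxia replicate 1 (0.245), and the mean score difference of -0.59 was -0.17 without it and -0.93 without hypoxia replicate 2. In hypoxia with PTH against normoxia the cAMP list was not called (median 0.30, camera adjusted p = 0.678). Inflammation genes rose as a list (median 0.23, 0 over all genes by edgeR and 3 adjusted over the list alone, camera adjusted p = 0.00109, and adjusted p = 0.628 with an estimated correlation). The scores of the inflammation list overlapped between the groups (-0.42, 0.03 and -0.06 in hypoxia, 0.05, -0.11 and 0.34 with PTH), and their mean difference of 0.24 was 0.11 without hypoxia replicate 1 and 0.12 without PTH replicate 5. With PTH against hypoxia the adhesion molecule gene Vcam1 had 0.75 (SE 0.14, adjusted p = 0.36). In hypoxia against normoxia the inflammation list was called lower (median -0.13, 1 gene higher and 1 lower over all genes, and 1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.449 with an estimated correlation). That call was lost without hypoxia replicate 1 (0.109), where the mean score difference was -0.07 from -0.21, and with the muscle and fat score as a covariate. Neutrophil markers were lower with PTH than in hypoxia, against the direction of the inflammation list in that comparison.

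Lower with PTH than in hypoxia were markers of airway, muscle, fat, neutrophils and NK cells. Ciliated cell markers fell as a list (16 of 17 below 0, median -0.63, 0 over all genes by edgeR and 13 adjusted over the list alone, camera adjusted p = 5.77e-09, and adjusted p = 0.628 with an estimated correlation). Club cell markers fell too (median -0.47, 0 over all genes by edgeR and 3 adjusted over the list alone, camera adjusted p = 0.000996, and adjusted p = 0.628 with an estimated correlation). Its member Cyp2f2 had -0.53 (SE 0.14, adjusted p = 0.426). Cardiac muscle (median -1.74, camera adjusted p = 5.53e-07), smooth muscle (-0.46, 0.000319) and NK markers (-0.53, 6.63e-05) fell as lists, each with adjusted p = 0.628 with an estimated correlation and with 0 genes called by edgeR over all genes or adjusted over the list alone. Adipocyte markers fell as a list as well (median -2.32, 0 over all genes by edgeR and 1 adjusted over the list alone, camera adjusted p = 0.026, and adjusted p = 0.656 with an estimated correlation). The adipocyte call was lost without hypoxia replicate 2 (0.1), hypoxia replicate 5 (0.288), PTH replicate 3 (0.067) or PTH replicate 5 (0.0557). Neutrophil markers fell as a list (16 of 16 below 0, median -1.59, 0 by edgeR over all genes or adjusted over the list alone, camera adjusted p = 0.00226, and adjusted p = 0.656 with an estimated correlation). That call was lost without hypoxia replicate 2 (0.311) or PTH replicate 4 (0.056) and with the muscle and fat score as a covariate (median -0.76). The neutrophil scores were -1.24, 2.12 and 0.56 in hypoxia and -0.06, -1.16 and -0.93 with PTH, and their mean difference of -1.20 was -2.06 without hypoxia replicate 1 and -0.38 without hypoxia replicate 2. Mean score differences of other lists also moved with single libraries. That of club markers (-1.07) was -1.64 without hypoxia replicate 1, -0.69 without hypoxia replicate 2 and -0.68 without PTH replicate 3, and that of NK markers (-0.60) was -0.96 without PTH replicate 3 and -0.36 without PTH replicate 4. That of cardiac markers (-1.95) was -0.96 without PTH replicate 5, and that of adipocyte markers (-1.45) was -2.39 without hypoxia replicate 1 and -0.95 without hypoxia replicate 2. Beside these lists stand the libraries' muscle and fat scores, which were -0.53, 1.44 and 1.7 in hypoxia and -0.24, -0.04 and -2.39 with PTH. With that score as a covariate the club (median 0) and smooth muscle (-0.03) lists were no longer called. The cardiac and adipocyte lists lost their calls too, which follows from the score being made of their markers. The smooth muscle list shares Actc1 with the cardiac list, so its loss is not wholly independent of the score. The ciliated list kept its call at a median of -0.21 (camera adjusted p = 0.000931, with a range of 1.25e-10 to 0.628 over its alternatives). Clock genes fell as a list (14 of 18 below 0, median -0.87, 0 by edgeR over all genes or adjusted over the list alone, camera adjusted p = 0.00908, and adjusted p = 0.628 with an estimated correlation). It was lost without hypoxia replicate 1 (0.0915), hypoxia replicate 2 (0.0752) or PTH replicate 3 (0.0681). In total camera called 21 lists, 10 up and 11 down, and 10 with the muscle and fat score as a covariate. With an estimated correlation it called 0, and another split of the 6 libraries called up to 19.

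Hypoxia with PTH was also compared with normoxia, which takes both treatments together. The genes given first stayed called with any of the 9 libraries left out, and some others with rises as large did not. Among those that rose were Ntrk2, to 276 ± 92.2 from 5.72 ± 1.13 CPM (n = 3 each, 5.60, SE 0.33), Slc26a10 (4.46, SE 0.12), Fam181b (2.44, SE 0.25), Adam23 (2.34, SE 0.22), Cxcl12 (2.14, SE 0.22) and Aspn (2.08, SE 0.22). Mfap4 rose by 1.95 (SE 0.12), Fn1 by 0.97 (SE 0.08) and the collagen gene Col6a3 by 0.97 (SE 0.13, from 91.4 ± 14.7 to 178 ± 9.96 CPM). Emcn (1.14, SE 0.13), Prox1 (1.71, SE 0.20), Ccl21a (1.67, SE 0.10) and the mesothelial gene Upk1b (0.73, SE 0.08) also rose. Esm1 (-2.66, SE 0.29), Plvap (-2.19, SE 0.25), Cd300lg (-1.83, SE 0.195), Cx3cl1 (-1.65, SE 0.15), Dll4 (-1.37, SE 0.14), Cyp4b1 (-0.87, SE 0.11) and Ednrb, an endothelin receptor gene (-0.80, SE 0.10), fell. Igha, the IgA heavy chain gene, fell from 100 ± 7.01 to 34.7 ± 8.61 CPM (-1.53, SE 0.19). All of these had edgeR adjusted p between 8.68e-08 and 0.00871 and stayed called with any of the 9 libraries left out, with adjusted p up to 0.0422. With the replicate block, Fam181b, Fn1, Col6a3, Prox1, Upk1b, Esm1, Cd300lg, Cx3cl1, Dll4, Cyp4b1, Ednrb and Igha lost their calls. Their edgeR adjusted p with it ran from 0.053 to 0.127. In all 341 genes were called, 249 higher and 92 lower, and 154 with a log2 fold change of at least 1 in size. There were 3378 genes at an unadjusted p under 0.05 against 982 by chance, and the groups did not overlap for 22.8% of genes, where chance gives 10%.

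That count fell to 81 without normoxia replicate 2, 84 without normoxia replicate 3, 186 without PTH replicate 4 and 83 without PTH replicate 5. DESeq2 called 1422 genes, 786 higher and 636 lower. The muscle and fat score as a covariate left 162 genes and the clock score 76, of which 66 were among the 341. The clock score separated most normoxia libraries from all PTH libraries, and a covariate uses a degree of freedom. Calls lost with the clock score, of genes named below too, therefore cannot be told apart from lost power. Named genes called against normoxia in hypoxia with PTH numbered 61, and 22 of them stayed called with any of the 9 libraries left out.

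Against normoxia, matrix genes rose as a list in hypoxia with PTH. Of 42 genes 35 had values above 0 (median 0.74), 14 rose over all genes tested and 31 adjusted over the list alone (camera adjusted p = 5.51e-16, and adjusted p = 0.241 with an estimated correlation). Cell cycle genes rose as a list (26 of 32 above 0, median 0.94, 5 over all genes and 19 adjusted over the list alone, camera adjusted p = 1.25e-12, and adjusted p = 0.373 with an estimated correlation). Its members Kif20a (1.60, SE 0.27, adjusted p = 0.0237) and Cdc20 (1.23, SE 0.20, adjusted p = 0.0196), both genes of mitosis, lost their calls without normoxia replicate 2 (0.074 and 0.07), normoxia replicate 3 (0.0772 and 0.052), PTH replicate 4 (0.0609 and 0.0587) or PTH replicate 5 (0.0549 and 0.0731), and with the clock score as a covariate. Cdc20 overlaps Elovl1, and Kif20a overlaps Cdc23, more highly expressed genes on the other strand. NK and cytotoxic markers fell as a list (16 of 16 below 0, median -1.40, 5 over all genes and 15 adjusted over the list alone, camera adjusted p = 3.5e-13, and adjusted p = 0.373 with an estimated correlation). Its receptor gene Klrc2 fell by 2.25 (SE 0.35, adjusted p = 0.0161), a call lost without normoxia replicate 3 (0.0629) or PTH replicate 5 (0.0541) and with the clock score as a covariate, and Klr genes have paralogs that can share reads. Pericyte markers rose as a list (median 0.43, camera adjusted p = 3.04e-05, and adjusted p = 0.241 with an estimated correlation). Of these, 4 rose over all genes, and 8 rose and 1 fell adjusted over the list alone. Alveolar macrophage markers rose as a list (14 of 19 above 0, median 0.38, 3 over all genes and 9 adjusted over the list alone, camera adjusted p = 5.13e-05, and adjusted p = 0.373 with an estimated correlation). Its chitinase-like gene Chil3 rose by 0.68 (SE 0.10, adjusted p = 0.016), a call lost without normoxia replicate 2 (0.0613) or PTH replicate 5 (0.0639) and with the clock score as a covariate. The mean score difference of the alveolar macrophage list was 0.23, and 0.09 without normoxia replicate 5. B cell markers fell as a list (17 of 17 below 0, median -1.06, 1 over all genes and 14 adjusted over the list alone, camera adjusted p = 7.12e-09, and adjusted p = 0.488 with an estimated correlation). Erythroid markers fell with them (9 of 13 below 0, median -0.34, 0 over all genes by edgeR and 6 adjusted over the list alone, camera adjusted p = 0.00588, and adjusted p = 0.488 with an estimated correlation). That call was lost without PTH replicate 3 (0.0655), where the mean score difference was -0.09 from -0.34, and the difference was -0.58 without PTH replicate 4. Ciliated markers also fell (17 of 17, median -0.72, 0 over all genes by edgeR and 14 adjusted over the list alone, camera adjusted p = 8.52e-08, and adjusted p = 0.488 with an estimated correlation). By fry's one-way test the matrix (0.00688), pericyte (0.00552), cell cycle (0.0334), NK (0.0334), lymphatic (0.0334) and alveolar macrophage (0.0434) lists passed. Camera called 21 lists, 11 up and 10 down, 0 with an estimated correlation, and up to 20 in another split of the 6 libraries.

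Beside these groups, the clock score was 2.40, 2.67 and -2.47 in normoxia and -2.52, -1.68 and -2.45 with PTH, so 2 of the 3 normoxia libraries differed in clock phase from all PTH libraries. With the clock score as a covariate the matrix, cell cycle, NK and pericyte lists stayed called by camera, at medians of 0.66, 0.76, -1.63 and 0.42. The muscle and fat score was 1.09, -0.20 and -0.82 in normoxia and -0.24, -0.04 and -2.39 with PTH, and with it as a covariate the median of the ciliated list was -0.50 and that of the club list -0.43. Club markers fell against normoxia (10 of 12 below 0, median -0.63, 2 over all genes and 3 adjusted over the list alone, camera adjusted p = 0.00107, and adjusted p = 0.488 with an estimated correlation). Their mean score difference of -1.11 was -0.66 without normoxia replicate 2 and -0.72 without PTH replicate 3. Cardiac markers fell as a list (median -0.68, 0 by edgeR over all genes or adjusted over the list alone, camera adjusted p = 0.0457, and adjusted p = 0.782 with an estimated correlation). The cardiac call was lost without normoxia replicate 2 (0.506), normoxia replicate 3 (0.073), hypoxia replicate 2 (0.0615) or PTH replicate 5 (0.825), and with either score as a covariate. Its mean score difference of -1.05 was -0.56 without normoxia replicate 2, -1.59 without PTH replicate 3 and -0.05 without PTH replicate 5.

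Whether PTH moved the hypoxia genes further or back was asked of the 112 genes called between hypoxia and normoxia. In 48 of them (42.9%) PTH against hypoxia had the same direction as hypoxia against normoxia, 36 of 81 among the higher and 12 of 31 among the lower genes. Both comparisons use the hypoxia libraries, which pushes this share down. Simulated libraries with a hypoxia effect and no PTH effect gave 29.5 to 42.9% over the 112 genes with the smallest p and 26.4 to 32.7% over the genes called, and unchanged libraries gave 2.68 to 11.6% over the 112 genes. The simulations with a hypoxia effect called 725 to 862 genes in hypoxia against 112 here, so their effect was unlike that of these libraries and does not settle the comparison. The share was 56 without normoxia replicate 3, 55.3 without normoxia replicate 5 and 53.8 without hypoxia replicate 1. Of the genes called against normoxia, 68 were higher and 24 lower both in hypoxia and in hypoxia with PTH, Ntrk2, Mfap4 and Fn1 among the higher and Plvap, Esm1 and Dll4 among the lower. These 2 comparisons share the normoxia libraries. Simulated libraries with a hypoxia effect and no PTH effect shared 305 higher and 182 lower genes on average, from their larger number of calls. The 92 shared calls fell to 54 without normoxia replicate 2, 42 without normoxia replicate 3, 50 without hypoxia replicate 1 and 59 without hypoxia replicate 5. With an adjusted p under 0.1 they were 227, and 143 with no filter.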

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

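Limma-trend on the deposited log2 TPM and the 2 covariates were chosen after seeing the data, and the cause was not tested for any change given here unless stated. Counts of changed genes are given in the order hypoxia against normoxia, PTH against hypoxia, and PTH against normoxia. DESeq2 gave 795, 156 and 1422 genes, against 112, 0 and 341. A threshold of 0.1 gave 324, 0 and 833, and requiring an absolute log2 fold change of at least 1 gave 60, 0 and 154, each by its construction. No filter gave 198 genes for hypoxia. The replicate block gave 8 for hypoxia and 17 for PTH against normoxia, and for the latter the muscle and fat score gave 162 and the clock score 76. The block leaves far fewer residual degrees of freedom than the 6 of the main model, so its lower counts cannot be told apart from lost power. The same holds for the clock score, which separated most normoxia libraries from all PTH libraries and uses a degree of freedom. Hypoxia replicate 1 and PTH replicate 4 alone carry their numbers, so the block fits them exactly. For PTH against hypoxia, limma-trend gave 3 on the deposited log2 TPM, 3 with a pseudocount of 0.1, 3 with 5, 4 with quantile normalization and 6 with median centring. Pth1r against normoxia in hypoxia with PTH stood at 0.86 with the 6 samples compared, 0.90 with the block, 0.92 with the muscle and fat score and 0.85 with the clock score, and was not called in these 4. Lists called fell from 20, 21 and 21 to 0, 0 and 0 with an estimated correlation, and to 1, 1 and 6 with fry. The muscle and fat score left 10 for PTH against hypoxia. The shared calls were 227 at 0.1 and 143 with no filter, against 92. With each library left out, genes changed ran from 50 to 158, 0 to 1 and 81 to 359, lists called from 15 to 24, 15 to 23 and 19 to 24, the same-direction share from 35.7 to 56% and the shared calls from 42 to 97. Pth1r ran from 0.23 to 0.43, 0.42 to 0.62 and 0.75 to 0.91. Directions reversed for Dbp in PTH against normoxia with the clock score, of which it is part (0.14), for the adipocyte list in PTH against hypoxia with the muscle and fat score, of which it is part (camera adjusted p = 0.817), and for the cardiac list in PTH against normoxia without PTH replicate 5 (camera adjusted p from 0.00372 to 0.825 over the libraries left out). Among values of single named genes, 2018, 2095 and 2340 kept direction and side of the threshold, 79, 35 and 85 came to pass it and 150, 0 and 323 no longer passed it. Among values of single called lists, 230, 228 and 255 kept both and 70, 86 and 59 no longer passed. On simulated data edgeR recovered 40.3 to 55.2% of genes changed 2-fold, so genes with smaller changes are often missed at this number of samples and depth.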

Other observations

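The counts of splits were planned ahead of their results. The prediction for ciliated markers was written ahead of its result, but it rests on the muscle and fat score, which was added after the data were seen. The other 3 tests here, on type 2 markers, on the clock score and on B cell against erythroid markers, were chosen only after the result was seen, and the covariates were too.

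Targets of hypoxia-inducible factor were not called as a list moving one way in hypoxia (33 genes, median 0.05, camera adjusted p = 0.248, and adjusted p = 0.461 with an estimated correlation), but passed fry's test for change in either direction (adjusted p = 0.0027). Of these genes 0 rose and 1 fell by edgeR: Hilpda, a lipid droplet gene (-1.70, adjusted p = 0.00863, and 0.0554 without hypoxia replicate 1). Genes of BMP and TGF beta signalling (median 0.09, camera adjusted p = 0.396) and of the response to interferon (0.10, 0.396) were not called as lists in hypoxia. The list of smooth muscle markers had a median of 0.10 (camera adjusted p = 0.0638). Vascular tone genes were not called as a list moving one way in hypoxia (median 0.06, camera adjusted p = 0.283). They passed fry's test for change in either direction in hypoxia (adjusted p = 0.000174), with 1 gene lower over all genes. In hypoxia with PTH against normoxia they passed it too (adjusted p = 1.71e-05), again with 1 gene lower over all genes.

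Airway, muscle and fat markers were lower and type 2 alveolar markers higher in hypoxia with PTH than in hypoxia. With the muscle and fat score as a covariate the ciliated list had a median of -0.21, from -0.63, and stayed called (camera adjusted p = 0.000931), so less muscle, fat and large-airway tissue in the sampled lung may account for part of this change, and the test does not decide how much. A larger share of alveolar tissue would raise type 1 and aerocyte markers with type 2 markers. The type 2 score rose beyond the mean of those 2 scores by 0.38 (SD 0.1 within groups), in all 3 PTH libraries above all 3 hypoxia libraries. The type 2 list was singled out because it differed most clearly in these same libraries. The test could therefore hardly have come out otherwise, and it does not decide on that share. Type 1 markers were themselves called up (9 of 12 above 0, median 0.13, camera adjusted p = 0.0144, and 0.628 with an estimated correlation), a call lost without hypoxia replicate 2 (0.0686) or 5 (0.24), with quantile normalization and with the muscle and fat score (median 0.07), and their mean score difference of 0.14 was 0.22 without hypoxia replicate 1 and 0.09 without replicate 5, so it is weak evidence and a part played by tissue share stays open. An effect of PTH on type 2 cells stays open as a hypothesis, since the pattern was found and tested on the same libraries.

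The clock score was lower by 3.57 in hypoxia with PTH than in hypoxia. Its output genes were lower on average, and Arntl, Npas2 and Clock higher. The score also ranged over 5.14 among the 3 normoxia libraries, which received neither treatment, with both arms of the clock moving apart. Collection at different hours of the day is a candidate explanation, and hours are not given in the labels used here. An effect of PTH on the clock stays open, as all 3 PTH libraries lay on one side.

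Lymphocyte and erythroid markers were both called lower by camera in hypoxia than in normoxia, as less blood left in the hypoxic lungs could produce. Platelet markers were called lower too (14 of 14 below 0, median -0.28, camera adjusted p = 0.013, and 0.629 with an estimated correlation). That platelet call was lost without normoxia replicate 5 (0.197). Neutrophil markers were not called and leaned the other way (13 of 16 above 0, median 0.42, camera adjusted p = 0.544). The B cell score minus the erythroid score differed by -0.51 between hypoxia and normoxia (SD 0.56 within groups), within its spread, so less blood and fewer lymphocytes in the tissue cannot be told apart here. For the falls in hypoxia with PTH against normoxia, where erythroid markers were lower too, this was not tested.

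The 6 samples of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. For hypoxia against normoxia 1 of 10 splits, the real one, gave 112 genes, and the highest other gave 4. For PTH against hypoxia 10 of 10 gave at least the real 0, with 0 the highest other, by edgeR (1828 genes at an unadjusted p under 0.05, 156 by DESeq2 and 0 by limma-voom in the real split). For PTH against normoxia 1 of 10 gave 341, with 1 the highest other. By lists, 1 of 10 splits in each comparison gave as many as the real 20, 21 and 21, and the highest others were 18, 19 and 20.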
